A study of Mus musculus with 15 samples.

How the data were processed

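RNA was measured by sequencing in 15 tissue samples from female C57BL/6 mice aged 18 months, 7 of them heterozygous for Rps9 D95N, a substitution in a protein of the small ribosomal subunit, and 8 of them wild-type littermates. The series design names brain cortex, while the tissue field of each sample names skeletal muscle, so marker genes of both tissues were looked at first. Per the labels' protocols, frozen tissue was extracted with Trizol and libraries followed standard Illumina protocols. The deposited values are raw read counts per Ensembl gene, 1 table per sample. Per the submitters' processing notes, the authors used STAR and featureCounts with the GRCm38 build. Versions, annotation, strand setting and the handling of reads that match several places are not given in the sources used here, so genes that overlap or have near-identical copies are uncertain.

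Each table held 22524 gene identifiers, of which 22291 matched GENCODE M21, an annotation of the same build, and 233 did not. Total counts per library ran from 23349381 to 34587082. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and in Python 3.11.15. Groups were taken from the genotype labels. No label gives a batch, litter or date, so none could enter a fit.

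The main test was edgeR's quasi-likelihood test on the counts as deposited, with TMM factors, the default expression filter, genotype as the 1 term and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM, counts scaled to a common library size, were computed here from the deposited counts with TMM factors, except for the tissue markers, which were scaled by library totals. Of 58 gene lists fixed before the data were examined, 57 with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. List members not matched to a row were not analysed here. Differences of library measures were tested by a two-sided exact permutation test over all 6435 regroupings.

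Named genes followed a rule fixed before the data were examined. It takes Rps9, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM, and up to 4 called members of each list by smallest p, or up to 2 as values where none was called. For other cell types and regions it adds up to 3 members of highest mean CPM, a part that was not applied. Not every gene the rule takes is printed, and some are not reported here. Gfap was chosen after its values were seen.

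The test was checked on simulated counts with the real means, library sizes and dispersions and 200 changed genes. Over 14926 genes of the simulated D95N against wild-type comparison, it recovered 58% of genes changed 1.2-fold, 82% at 1.5-fold, 90% at 2-fold and 96% at 3-fold, with 10 false calls. Genes were simulated independently of each other, with 1 dispersion per gene for both genotypes. In the data genes vary together, the spread was larger in D95N and 26.8% of genes passed. The simulated rates therefore need not hold for these data. Alternatives covered scaling, filters, DESeq2, limma-voom, a surrogate variable, region scores as covariates, libraries of low correlation and each library left out in turn. Added after the data were seen were thinning to the shallowest total, leaving out the 2 shallowest libraries, a correction for GC content and length, and blood and meningeal scores as covariates.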

Results

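Transcripts were counted in 15 libraries, 7 from heterozygous Rps9 D95N mice and 8 from wild-type littermates, to ask how the cortex of aged animals differs when 1 copy of a ribosomal protein gene carries this substitution. Samples are named by genotype and animal number. Neuronal, astrocyte and oligodendrocyte markers were abundant in every library and muscle markers were near the floor, against the tissue field of the labels. Snap25, a synaptic vesicle fusion protein, stood at 2798 ± 132 CPM (SD) over the 15 libraries and Acta1, skeletal muscle actin, at 6.18 CPM. The mean over the skeletal muscle list was 4.17 to 7.83 CPM per library, with the highest value in wild-type 19, and that over the pan-neuronal list 694 to 727 CPM. Total counts averaged 28994834 ± 3924638 (SD, n = 7) in D95N and 31533298 ± 2071895 (SD, n = 8) in wild type, a difference within the spread between libraries (exact permutation test, two-sided, p = 0.14). Mitochondrially encoded genes took 3.76% ± 0.371 and 3.89% ± 0.174 of counts (exact permutation test, two-sided, p = 0.416).

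Rps9 (ENSMUSG00000006333) lies on chromosome 7 from 3703993 to 3706897 of GRCm38. Residue 95, counted from the first methionine, is encoded at 3705795 to 3705797, in exon 4 of 5 of transcript Rps9-201. Its transcript stood at 63.1 ± 6.13 CPM (SD, n = 7) in D95N and 65.3 ± 3.02 CPM (SD, n = 8) in wild type, a log2 fold change of -0.05 ± 0.05 (SE) that did not pass the test (edgeR, adjusted p = 0.505). Gene counts cannot show the substitution, so this level does not check the genotype labels.

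The gene of smallest p was Eef1a2 (ENSMUSG00000016349, chromosome 2, 181147653 to 181157014), the form of the factor that brings aminoacyl-tRNA to the ribosome in mature neurons. It fell from 1021 ± 14.2 CPM (SD, n = 8) in wild type to 711 ± 39.0 CPM (SD, n = 7) in D95N, and all 7 D95N libraries lay below all 8 wild-type libraries. Its log2 fold change was -0.52 ± 0.03 (SE; edgeR, adjusted p = 1.2e-07). Eef1a1, the more widely expressed form, fell from 469.7 to 378 CPM, also in 7 of 7 libraries. Lpl, lipoprotein lipase, fell by 0.65 on the log2 scale in 7 of 7 libraries. Of 39 translation factors tested, Eef1a2 and Eef1a1 included, 7 rose, among them Eif3b at 1.23-fold, and 4 fell (3 and 7 with library totals, 5 and 5 with upper-quartile factors, 9 and 5 with a GC and length correction). Of 72 cytosolic ribosomal protein genes 4 rose, Rps2 among them, and 3 fell, among them Rpl5 with a log2 fold change of -0.35 (4 and 7 with library totals or upper-quartile factors, 6 and 6 with the correction, 5 and 6 of 78 by DESeq2). Ribosomal protein genes have many near-identical copies, so their counts are uncertain.

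Genes that neurons switch on with activity included some of the large increases. Nptx2 (ENSMUSG00000059991, chromosome 5, 144545902 to 144557478), a pentraxin secreted at excitatory synapses, rose 9.21-fold, from 39.7 ± 9.36 CPM (SD, n = 8) to 366 ± 186 CPM (SD, n = 7), with a log2 fold change of 3.20 ± 0.37 (SE; edgeR, adjusted p = 0.000112). Bdnf, a neurotrophin, rose 4.24-fold and Inhba, an activin subunit, 5.62-fold. Of 24 tested activity-induced genes 14 rose and 1 fell, and 15 and 1 when adjusted over the list alone, with Egr3 at 2.62-fold and Gadd45b at 3.24-fold. Homer1, a postsynaptic scaffold, rose 1.80-fold, Npy, a neuropeptide, 2.94-fold, and the presynaptic genes Bsn and Syn2 1.29-fold and 1.48-fold. The D95N libraries were uneven here: Nptx2 ran from 214 CPM in D95N 41 to 579 CPM in D95N 28, but was 40.6 CPM in D95N 42, inside the wild-type range of 28.5 to 55.9 CPM. The largest increase was in Slc6a5, a glycine transporter (15.8-fold, from 2.60 to 40.6 ± 52.3 CPM), where D95N 4 and 44 stood at 135 and 94.5 CPM and the others at 4.38 to 19.1 CPM, and its log2 fold change of 3.98 was 3.27 without D95N 4. Others were Drd4, a dopamine receptor (15.4-fold), Htra4 (9.65-fold), Acaa1b (8.83-fold), Cryba2, Adgrf4, Lhx3, Rgs13, B3gnt8 and Cd28. Most of these folds start near the floor. Wild-type means were 0.289 CPM for Drd4, 0.949 CPM for Htra4, 0.353 CPM for Acaa1b and 1.66 CPM for Adgrf4. They were 0.246 to 0.589 CPM for Cryba2, Lhx3, Rgs13, B3gnt8 and Cd28. In each of these genes but Lhx3, D95N 42 lay within the wild-type range. Without D95N 4 the log2 fold changes of Cd28 and Adgrf4 went from 3.17 and 3.04 to 2.56 and 2.23, and both passed. Cyp2a5 rested on D95N 21, at 21.6 CPM against at most 1.12 CPM in the other D95N libraries, and without it the log2 fold change was 1.03 with an adjusted p of 0.0746.

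**Figure D1:**
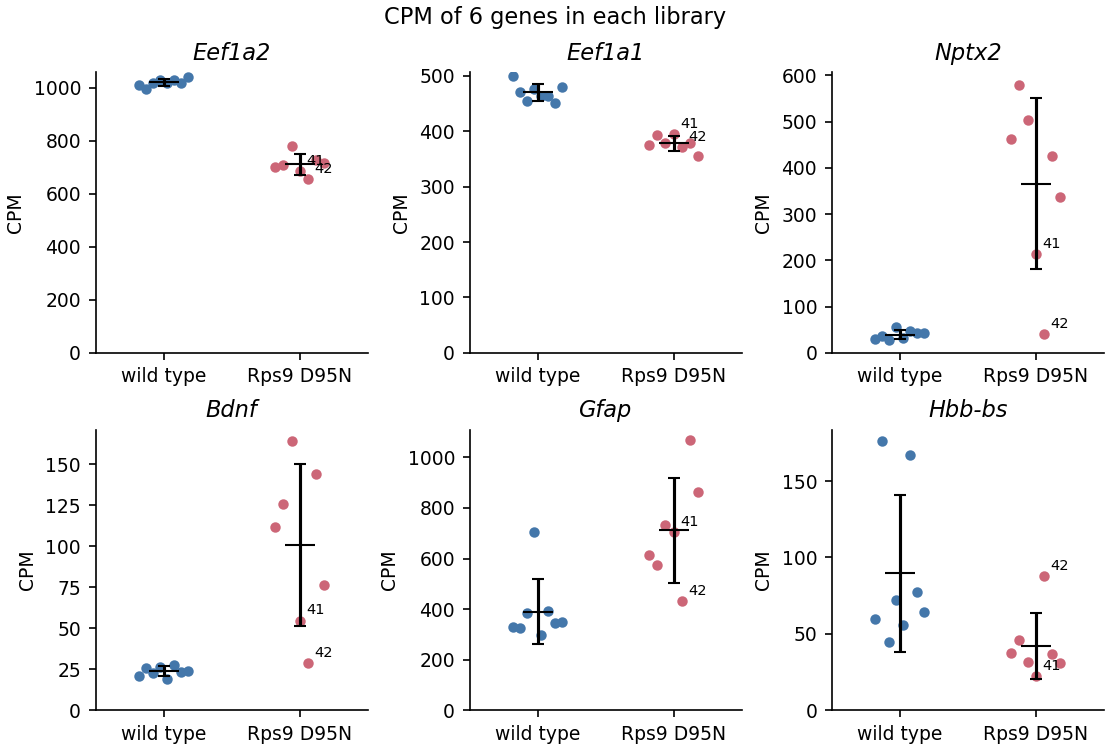
CPM of 6 genes in each library (points), with group means and SDs (black), for 8 wild-type and 7 Rps9 D95N libraries. Eef1a2 is lower in all 7 D95N libraries, while Nptx2 in D95N 42 is 40.6 CPM, within the wild-type range.

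Glial genes moved in both directions. Of 21 genes of reactive astrocytes 10 rose and 2 fell (8 and 2 with library totals), with Serpina3n at 2.08-fold, Aspg at 2.79-fold and Cd44 at 2.27-fold. Gfap, the astrocyte filament protein, rose 1.82-fold, although wild-type 24 stood at 704 CPM, within the D95N values. Of 18 general astrocyte genes 10 fell and none rose, among them Slc1a3, a glutamate transporter, at 0.857-fold, Slc4a4 and Gja1. None of 16 homeostatic microglia genes passed the test by edgeR (4 at an unadjusted p under 0.05, and called lower were 1 by DESeq2, 1 with the GC and length correction, 2 with upper-quartile factors and 3 with library totals), with Mertk at a log2 fold change of -0.22 (adjusted p = 0.0556) and Csf1r at -0.14 (adjusted p = 0.0783). Of 27 genes of disease-associated microglia 5 rose, including Gpnmb at 2.54-fold and Cd68 at 1.30-fold, and 4 fell (4 and 5 with library totals). Among those that fell were Lpl, the member of smallest p, at 0.639-fold and Csf1 at 0.885-fold, each in 7 of 7 D95N libraries. Of 14 complement genes 3 rose, C4b at 1.55-fold and C1ra at 1.87-fold among them, and 1 fell.

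Of 74 nuclear-encoded respiratory chain genes 29 rose and 1 fell (19 and 2 when scaled by library totals, 38 and 1 with a GC and length correction), with Ndufb9 at 1.21-fold and Ndufv3 at 1.18-fold. Proteasome genes rose in 8 of 35 (7 with library totals, 17 with the GC and length correction, where 1 fell), Psmd3 at 1.12-fold and Psmb7 at 1.13-fold. In the integrated stress response list 12 of 33 rose and 2 fell (8 and 4 with library totals, 10 and 2 with the GC and length correction). Atf3 rose 5.74-fold, with D95N 28 at 18.8 CPM and the other D95N libraries at 0.905 to 5.53 CPM, and its log2 fold change of 2.52 was 1.85 without D95N 28. Cebpb rose 1.97-fold and Asns 1.12-fold, while Phgdh fell. In the unfolded protein response list 7 of 29 rose, Wfs1 at 1.98-fold, Sdf2l1 at 1.32-fold and Hyou1 at 1.13-fold. Of 20 ubiquitin ligase and extraction genes 6 rose, among them Ubr4 and Uchl1. Of 30 amyloid and tau pathway genes 9 rose and 3 fell (6 and 5 with library totals), Mapt (tau) to 0.884-fold and Gsk3b, a tau kinase, to 0.885-fold. Scaled by library totals, 4 of the ubiquitin list were higher and 2 lower, and 6 and 1 of the unfolded protein list. With the GC and length correction 9 and 10 were higher and none lower.

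Of 11 blood cell genes 9 fell, with Hbb-bs at 0.466-fold, Hbb-bt at 0.372-fold and Hba-a1 at 0.505-fold, and of 16 meningeal fibroblast genes 6 fell and 1 rose, with Slc6a13 at 0.499-fold, Slc22a6 at 0.519-fold and Ogn at 0.547-fold. Of 16 striatal genes 7 fell, among them Gpr6 at 0.620-fold. Among the other large decreases were Clspn, Nlrp6, Tcap, Alas2 and Ntf3. Their levels were low, with wild-type means of 6.38 CPM for Alas2 and 1.90 to 2.95 CPM for the others. The neutrophil genes S100a8, S100a9 and Ngp were highest in wild-type 32, and so was Lrg1, which is not in the blood cell list. Without it S100a8 passed at a log2 fold change of -1.74, and S100a9, Ngp and Lrg1 did not pass, at -1.18, -1.39 and -0.99. Cbln3, a cerebellar granule cell gene, was called for 1 library, wild-type 19, at 23.7 CPM against at most 0.647 CPM in the others of either genotype, and its log2 fold change was -0.20 without it. Alas2 lost its call without any of several single libraries, with an adjusted p of 0.0925 without wild-type 32.

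In all, 4016 of 14989 tested genes (26.8%) passed, 2272 higher and 1744 lower in D95N, and 196 and 26 of these changed at least 2-fold. All 7 D95N libraries lay above all 8 wild-type libraries in 271 genes and below in 220, where chance gives 0.0311% of genes for both directions together. The split depends on scaling: with upper-quartile factors 1926 were higher and 2351 lower, and with library totals 1808 and 2536. With scores for oligodendrocytes, choroid plexus and striatum in the fit 2268 genes passed, and with blood and meningeal scores 125. The 11 lists that camera called at the preset correlation are those in the plot of list members, and none held with an estimated correlation (adjusted p = 0.681 for the striatum and 0.608 for each of the others). Adjusted over the list alone, the members higher and lower were 32 and 1 for the respiratory chain, 11 and 0 for the proteasome, 15 and 3 for the integrated stress response, 10 and 3 for reactive astrocytes, 7 and 0 for both the unfolded protein and the ubiquitin list, 0 and 10 for both astrocytes and blood cells, 1 and 6 for meningeal fibroblasts and 0 and 7 for the striatum. Other splits of the same 15 libraries into 7 and 8 gave a median of 11 called lists, so the list calls do not stand apart from chance. The counts above are of single genes, to be read against the 26.8% of all tested genes that passed. Some lists lay below that share, such as the proteasome (8 of 35), the unfolded protein response (7 of 29) and cytosolic ribosomal proteins (4 higher and 3 lower of 72). Others lay above it, such as the activity list (14 higher and 1 lower of 24). A count near or below that share does not set a list apart from other genes. That share covers both directions and the main scaling alone. Among all tested genes 2272 of 14989 were higher, and the proteasome and unfolded protein lists had no member lower. With the GC and length correction 17 of 35 proteasome genes were higher and 1 lower. Of the unfolded protein list 10 of 29 were then higher, against 4403 of 14928 genes called in either direction.

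**Figure D2:**
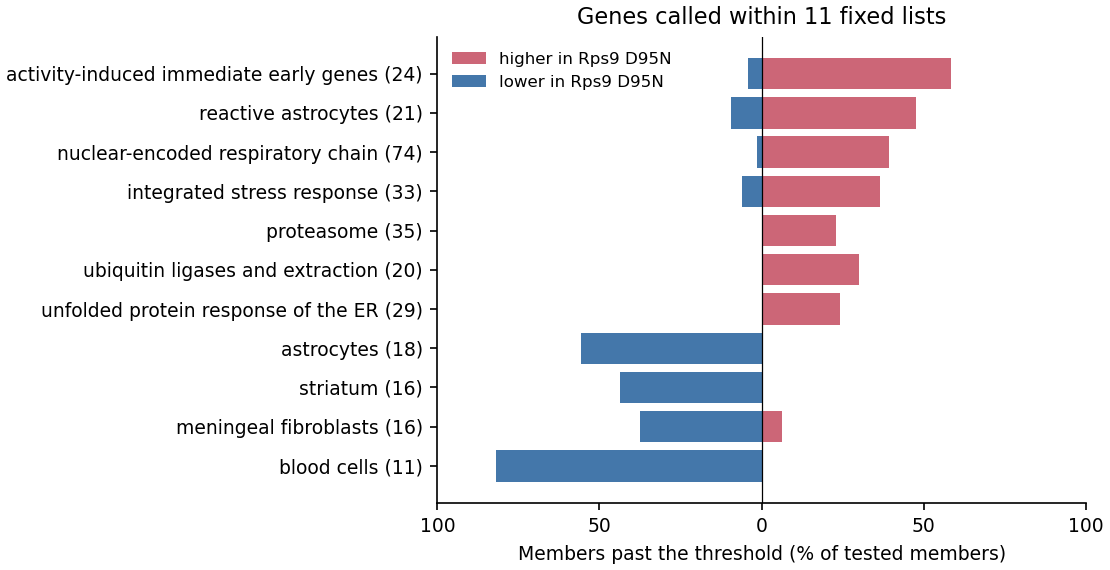
Percent of tested members called higher (right) or lower (left) in Rps9 D95N for the 11 lists called by camera at the preset correlation, with the number tested in parentheses. In the activity list 14 of 24 members were higher, and in the blood cell list 9 of 11 were lower.

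The D95N libraries differed more among themselves than the wild-type libraries did. The median SD of log2 CPM was 0.155 in D95N and 0.0903 in wild type, and 83.1% of genes had the larger SD in D95N. The first principal component of log2 CPM, with 37.8% of the variance, placed the 8 wild-type libraries between 10.6 and 19.4, 5 D95N libraries between -32.5 and -22.5, D95N 41 at -4.89 and D95N 42 at 13.9. Those 5 D95N libraries also had low median correlations with all other libraries, most of which are wild type. Such a median partly reflects distance from the wild type, so it is not separate evidence of poor libraries. Without these 5, which leaves D95N 41 and 42, 193 genes passed. That fit leaves out the D95N libraries farthest from the wild type on the first component.

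**Figure D3:**
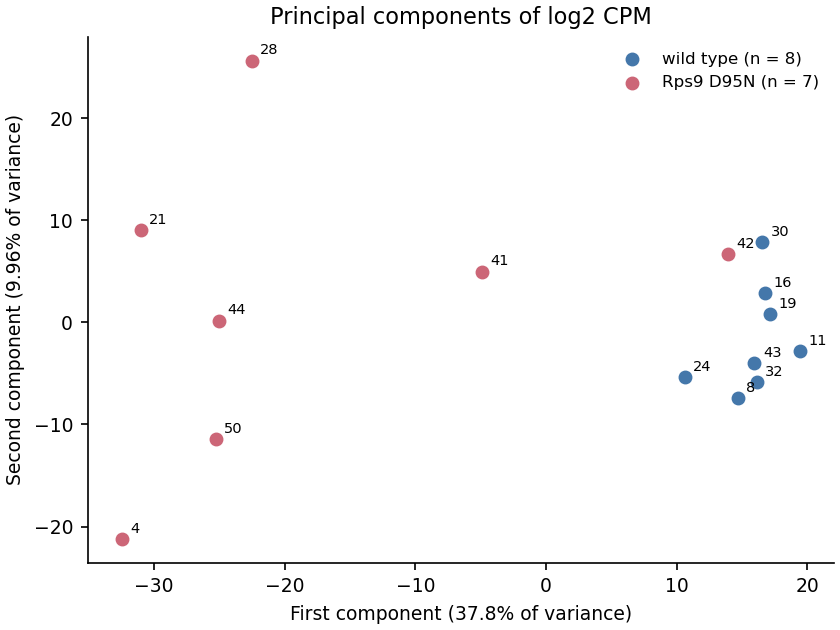
First (37.8% of variance) and second (9.96%) principal components of log2 CPM for 8 wild-type and 7 Rps9 D95N libraries, each point 1 library with its animal number. D95N 42 lies at 13.9 on the first component, among the wild-type libraries.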

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

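All tests in this part that weigh library D95N 42, the activity-regulated genes and the blood and meningeal transcripts were chosen after the results were seen, and the counts over other splits were planned.

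Of 100 splits of the 15 libraries into 7 and 8, the real one included, 1 gave at least 4016 called genes, 1 at least 2272 higher and 1 at least 1744 lower. As the real split is among them, 1 of 100 is the smallest share this test can give. Chance is thus unlikely for the gene counts but not excluded. The highest of the other splits gave 2093, 1120 and 1310, and their median was 0. For gene lists chance cannot be excluded: 57 of the 100 splits called at least 11 lists, up to 22.

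Library D95N 42 lay near the wild type on the first component. A share of wild-type RNA mixed into D95N RNA would shift all genes by a like share, but the library had 20.1% of the shift of the other 6 in genes changed under 1.25-fold and -0.342% in those changed at least 2-fold, a difference of 0.204 (bootstrap over genes 0.178 to 0.23; wild-type libraries left out in turn gave at most 0.105). A wild-type library under a D95N label is argued against by the last of 4 versions of a test, chosen after the values of Eef1a2 (656 CPM, -25.8 SDs from the wild-type mean) and Eef1a1 (371 CPM, -6.41 SDs) were seen: among 393 to 446 separating genes of at least 100 CPM, picked without it and without 1 wild-type library, it lay over 5 SDs of the other 7 wild types away on the D95N side for 16 to 23 genes, and the wild-type library left out for at most 13, fewer in each of 8 pairings. In the first 3 versions it did not pass every wild-type library, with 32.7% of separating genes on the D95N side against up to 35%, 31.6% against up to 33.6% with matched gene sets, and 5 of the 20 genes of smallest p against up to 15, the wild-type highest being animal 24 each time, and 1 of 9 libraries ranks first by chance in 11.1%. Why a D95N animal would differ less from the wild type stays open, and without this library 4976 genes passed.

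The mean of the activity-regulated genes lay above every wild-type library in 4 of 7 D95N libraries. More or less white matter, choroid plexus or striatum in the D95N samples is argued against, since with their scores in the fit the fold changes of the 24 genes kept a slope of 0.994 on those without (0.891 to 1.09 leaving out 1 library), although 9 rather than 15 passed. Any of hippocampus, olfactory bulb, thalamus or cerebellum alone is argued against as the whole source, with slopes of 0.975, 1.05, 1.05 and 0.771 (lowest leaving out 1 library 0.888, 0.992, 0.998 and 0.616) and 11, 13, 16 and 8 genes passing, but a mix of the 4 cannot be told apart from the genotype, since the slope was 0.914 but 0.461 without wild-type 19. Rapid minus delayed genes differed by -0.366 on the log2 scale (exact two-sided permutation p = 0.11). By itself this difference does not separate a brief burst of activity at death from lasting activity. The 14 delayed genes were higher by 0.999 (exact two-sided permutation p = 0.000777), and by 0.924 to 1.16 leaving out 1 library. Their mean lay above every wild-type library in 6 of 7 D95N libraries, and that of the rapid genes in 2 of 7. A burst too brief for delayed genes to respond is argued against for the rise of these 14 genes. It stays open for the rapid genes, which were higher by 0.633. Genes were classed as rapid or delayed with the increases in view, which limits this reading. The genotype stays open as an explanation and so does an unrecorded difference in handling.

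Of 11 blood cell genes 9 were lower in D95N, and of 16 meningeal genes 6 were lower and 1 higher. Less blood left in the tissue stays open for the red-cell genes, whose log2 fold changes differed by 0.439 at most, within the bound of 0.79 set by their errors. Those errors hold variation between libraries that the red-cell genes share. The bound is therefore wide, the test could hardly have failed, and it does not single out blood left in the tissue. The loss of blood and meninges together is argued against as the source of the larger changes among the other calls. Their fold changes kept a slope of 0.862 (0.77 to 0.993 leaving out 1 library) with blood and meningeal scores in the fit. Large changes dominate this slope, so it says little of the many small ones (median fold 1.21 for genes called higher and 0.849 for genes called lower). In the fit with these scores 125 genes passed rather than 4016, as the median SE rose from 0.0643 to 0.0979 (variance inflation 2.41): the folds without scores tested with the SEs of that fit gave 50 calls, and its folds with the SEs without scores 4313.

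A sample stood far from the rest of its group in 25 of 188 groups of values, where chance gives about 1 in 20 for independent, normally spread values. Of the 94 items behind these groups 78 were genes named here, many picked for large changes, and some move together. The 1 in 20 therefore does not hold for them, and no excess is read from the count. In wild-type 32 the 10 most abundant genes took 5.48% of counts and mitochondrial genes 4.3%, and S100a8, S100a9, Ngp and Lrg1 stood at 9.53, 10.3, 5.53 and 15.2 CPM. Wild-type 24 stood apart in Rps9 (58.4 CPM), Gadd45b (13.1 CPM), Gfap (704 CPM), Drd4 (0.834 CPM) and the mean log2 CPM of the unfolded protein response list (5.98). Wild-type 19 stood apart in Cbln3 (23.7 CPM) and wild-type 8 in Ndufv3 (44.1 CPM). D95N 42 was the highest of its group in Hba-a1 (20.9 CPM), Hbb-bt (16.7 CPM), Hbb-bs (87.8 CPM), Alas2 (6.48 CPM) and Nlrp6 (2.26 CPM). D95N 28 stood apart in Psmd3 (159 CPM), Atf3 (18.8 CPM) and Cd68 (17.6 CPM), D95N 21 in Cdkn1a (153 CPM) and Cyp2a5 (21.6 CPM), and D95N 4 in Cd28 (10.7 CPM) and Adgrf4 (48.4 CPM).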

How the results depend on the processing

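The settings with blood and meningeal scores, GC and length, thinning and the 2 shallowest libraries left out were chosen after seeing the data. Against 4016 genes (2272 higher, 1744 lower), the count was 2268 (1354 and 914) with region scores as covariates, 193 (115 and 78) without the libraries of low correlation, which leaves 2 D95N libraries, and 125 (67 and 58) with blood and meningeal scores. Region scores also widened the errors (median SE ratio 1.4). The folds without scores tested with the SEs of that fit gave 1243 calls, and its folds with the SEs without scores 5330. Leaving out 1 library gave 3263 to 4976 genes, and the other settings at an adjusted p under 0.05 gave 3361 to 4490. A looser threshold of 0.1, under which more genes pass, is left out of this range. The lists past the threshold went from 11 to 0 with an estimated correlation, 22 with fry and 17 with the GC and length correction, and to between 9 and 14 leaving out 1 library. The cause was not tested. Rps9 passed under no setting (log2 fold change -0.11 to -0.02). Eef1a2 passed under each, at -0.63 to -0.50, and Nptx2 under each, at 1.68 to 3.40, while Gfap passed under 28 of 31, main setting included.

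Without the libraries of low correlation the direction turned for Cyp2a5 (-0.26), Cd28 (-0.15), Irf7 (-0.16), Dnajb5 (-0.02), Bop1 (-0.0265), Srebf2 (-0.0239) and Ntng1 (0.0456). With blood and meningeal scores it turned for S100a8 (0.42), S100a9 (0.52), Ngp (0.64), Ly6a (0.0133) and Rora (0.038). The cause was not tested. The wild types were littermates, but no label gives the litter, so no analysis paired by litter was possible. Depth ran from 23349381 to 34587082 counts, and thinning to the shallowest total gave 3808 genes, so depth is not what sets the count.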

Other observations

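The test of gene families in this part was chosen after the results were seen. Several clock genes changed: of 17 tested 2 rose and 6 fell, with Hlf at 0.651-fold, Dbp at 0.738-fold and Nr1d1 at 0.787-fold, while Nfil3 rose 1.47-fold. This list was fixed beforehand as genes that move with the hour of dissection. No label used here gives that hour, so it cannot be told apart from the genotype. Of 15 GABA receptor genes 4 fell, Gabra5 to 0.732-fold, and of 25 glutamate receptor genes 2 rose and 6 fell. Cdkn1a, a cell cycle inhibitor, rose 2.97-fold. Of 53 mitochondrial ribosomal protein genes 14 rose and 3 fell, and of 27 presynaptic genes 11 rose and 3 fell.

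Among genes grouped by the stem of their symbol, all 12 tested protocadherin alpha genes were lower, by a fold of 0.864 to 0.876. These genes share exons, so their counts can hold the same reads and the 12 are not independent of each other, so no p is given. In 368 tests of the other families by Fisher's exact test with Benjamini-Hochberg adjustment none passed, the smallest adjusted p being 0.0969 for genes with the stem Atp, of which 23 of 72 were higher and 8 lower. With protocadherin alpha included, over 370 tests, the adjusted p of the Atp genes by Fisher's exact test was 0.0487, under 0.05. Their call thus depends on which families are counted.

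For the remaining lists, the genes that rose and fell were as follows, to be read against the 26.8% of all tested genes that passed in either direction. None rose in DNA repair (1 of 28 fell), choroid plexus (1 of 18), ependyma (1 of 13), endothelium (4 of 16), olfactory bulb (3 of 16), cerebellum (2 of 12), thalamus (2 of 14), skeletal muscle (1 of 13) and histones and other RNA without poly(A) tails (2 of 5). None fell in cholesterol synthesis (4 of 22 rose), mitochondrial quality control (3 of 16), the NF-kB response (3 of 19), heat shock (6 of 25), the glucocorticoid response (3 of 18) and genes next to Rps9 (2 of 18). Pericytes had 1 higher and 5 lower of 14, ribosome quality control 5 and 1 of 21, interferon response 1 and 4 of 29, lysosome 8 and 1 of 33, senescence 5 and 3 of 14, pan-neuronal genes 4 and 2 of 16, and the NRF2 response 5 and 3 of 26. Ribosome biogenesis had 6 and 3 of 30, MHC class I 1 and 2 of 15, the p53 response 5 and 1 of 28, cortical layer neurons 6 and 8 of 22, perivascular and lymphoid cells 1 and 3 of 8, the postsynaptic density 7 and 4 of 24, autophagy 4 and 2 of 27, and hippocampus 4 and 3 of 15. Oligodendrocytes had 1 and 2 of 18, their precursors 2 and 1 of 15, interneurons 8 and 3 of 21 and calcium handling 6 and 6 of 36. None of 7 mitochondrially encoded genes passed by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2, and 2 higher with the GC and length correction), and none of 2 pituitary genes (0 at an unadjusted p under 0.05, 1 by DESeq2).

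The counts in this part depend on the scaling, and those that moved by at least 2 genes, or changed which direction had more, with library totals or with the GC and length correction are given here as genes higher and lower. With library totals they were 6 and 4 for lysosome, 4 and 3 for the p53 response, 0 and 3 for DNA repair, 3 and 1 for ribosome quality control, 4 and 0 for heat shock and 10 and 4 for mitochondrial ribosomal proteins. They were 9 and 4 for presynaptic genes, 2 and 8 for both glutamate receptors and the clock, 6 and 3 for interneurons, 4 and 4 for pan-neuronal genes, and 3 and 3 for both autophagy and the NRF2 response. More were lower than higher in ribosome biogenesis (4 and 5), hippocampus (2 and 3), oligodendrocyte precursors (1 and 2) and calcium handling (4 and 6), and genes next to Rps9 had 1 and 1. With the GC and length correction the counts were 6 and 7 for the postsynaptic density, 2 and 5 for hippocampus, 1 and 2 for oligodendrocyte precursors, 4 and 6 for calcium handling, 1 and 3 for DNA repair, 9 and 5 for presynaptic genes, 11 and 3 for mitochondrial ribosomal proteins, 5 and 0 for mitochondrial quality control, 6 and 1 for pan-neuronal genes and 0 and 0 for choroid plexus. With upper-quartile factors the lysosome had 6 and 3.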
